A study of Mus musculus with 6 samples.

How the data were processed

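RNA of 6 samples of adult mouse kidney was measured on Affymetrix Mouse Gene 2.1 ST arrays, 1 array per sample. Per the labels, 3 arrays come from mice with conditional Pax2 and Pax8 alleles and a tamoxifen-inducible Cre recombinase at the Rosa26 locus. They are called the arrays labelled knockout, and are replicates 1, 3 and 5. The other 3 arrays, controls 2, 4 and 6, come from Cre-negative mice that also received tamoxifen. Each group holds 2 females and 1 male; the males are knockout 1 and control 4. The labels do not state for each array that it is a separate animal or when it was hybridised, so p-values measure the spread between these samples, and no batch could be tested. Tamoxifen was given at 50 mg/kg in 3 daily injections at 8 weeks of age and again at 10 weeks, and kidneys were taken 14 days after the last injection. Labelled cDNA was made from 400 ng of RNA.

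The deposited values are log2 expression values per transcript cluster. RMA, R 3.4.0 and limma are named in the submitters' processing notes without their roles; any filter and the package versions are not given in the sources used here. The scale was checked on the values, whose medians and quartiles were nearly equal on the 6 arrays, as RMA's log2 values are. The authors' values were used as deposited. The table holds 41345 clusters. The platform annotation gave 1 gene symbol for 23521 of them, several for 1814 and none for 16010. Symbols were looked up through the gene identifier in a RefSeq table of assembly GRCm38.p6, which matched 23328 of the 1-symbol clusters and changed no symbol. The other 193 kept the platform symbol. No genome build is given in the sources used here, so no coordinates are printed. Clusters with several symbols or none were left out of the main tests. Where a gene had more than 1 cluster (1082 genes), the cluster with the highest mean over the 6 arrays was used, which left 22180 genes.

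Differences were tested with limma 3.58.1 in R 4.3.3 on the log2 values, in a linear model with genotype and sex and limma's default empirical Bayes moderation (3 residual and 6.72 total degrees of freedom). Benjamini-Hochberg adjustment ran over all 22180 genes, with a threshold of 0.05 for the adjusted p. A log2 fold change is the value on the arrays labelled knockout minus that of the controls, adjusted for sex, and its error is limma's moderated standard error (SE). Group levels are means with the SD over 3 arrays. The sex effect came from the same model and the dependence of the genotype effect on sex from a genotype by sex term, with 2 residual degrees of freedom. For Pax2 and Pax8 an exact two-sided permutation test of the group means was added.

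Before the data were examined, 38 gene lists of nephron segments, other cell types and pathways were written, with 523 entries, of which 465 were measured through a cluster with 1 symbol. The other 58 were not analysed here. Of the 38 lists, 37 had at least 3 measured members and were tested with limma's camera with a preset correlation of 0.01, adjusted over the 37 lists. The red blood cell list had 1 measured member, Slc4a1, and was not tested, so blood content was not checked. Camera with an estimated correlation and fry were run as alternatives. The text names, by a rule of the same time, Pax2 and Pax8, the 12 largest rises and the 12 largest falls among called genes whose 3 knockout-labelled arrays all lay beyond the 3 controls. It also takes up to 4 members of each list with the smallest p, of which those that passed are printed, all members of the urea transporter and aquaporin list, the 5 largest sex differences each way with the sex chromosome genes, and the 5 smallest interaction p-values. Any other gene named was chosen after its values were seen.

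Alternatives fixed beforehand were a model without sex, females only, each array left out in turn, a trended robust prior, array weights, quantile normalization, median centring, removal of dim genes (mean log2 below 3.38), the average of a gene's clusters, and a test of every row. A test of the lists for dependence on sex (camera with both correlations, and fry), a test of gene families by symbol and single arrays left out of the sex tests and for genes named later were added after seeing the data. The fit and camera with the preset correlation were tested on simulated data. There were 20 simulations of the knockout-labelled against control comparison over 22180 genes with 200 changed genes. A log2 change of 0.5 was recovered in 26.0% of the changed genes, a change of 1 in 76.7% and a change of 2 in 96.4%, with 3.71% false calls. A list of 15 genes shifted by 0.5 was recovered in 20 of 20 simulations, with 0 of 740 unshifted lists called; simulated genes were independent, which real genes are not. The 6 arrays limit the precision.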

Results

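Gene expression was measured in adult kidneys labelled as carrying, or not carrying, an inducible deletion of Pax2 and Pax8, the paired-box transcription factors that direct kidney development and stay expressed in adult tubules. The series asked which transcripts change when both genes are lost in the adult. RNA came from bisected kidneys. There were 3 arrays labelled knockout and 3 control arrays, each group with 2 females and 1 male. The median log2 value per array lay between 3.81 and 3.87. Pearson's r between arrays, taken across genes, which are not independent replicates, ranged from 0.979 to 0.995. The male arrays, knockout 1 and control 4, were closer to each other (0.991) than to the females of their own groups. For knockout 1 the latter values were 0.988 and 0.989, and for control 4 they were 0.989 and 0.988. No pair of arrays held the same values at more than 29 of 41345 clusters. Xist and the Y-linked genes matched the sex label on 6 of 6 arrays.

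The targeted genes did not fall on the arrays labelled knockout. Pax8 (Entrez gene 18510) was 2.58-fold higher there, at 10.36 ± 0.24 log2 against 9.0 ± 0.10 (SD, n = 3 per group), a log2 fold change of 1.36 ± 0.12 (SE) with a limma adjusted p of 0.0037. The values were 10.11, 10.59 and 10.39 on the arrays labelled knockout 1, 3 and 5, and 9.09, 9.0 and 8.89 on controls 2, 4 and 6. Pax2 (Entrez gene 18504) stood at 6.25 ± 0.21 against 5.98 ± 0.18 (SD, n = 3), a log2 difference of 0.27 ± 0.10 (SE) that did not pass (adjusted p = 0.19). For both genes the exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays allow. Each gene has 1 cluster, which summarises probes over the transcript, and the labels do not say which exons are removed. Probes outside the deleted part check nothing, so these values neither bear out nor rule out the labels. Every direction below is therefore that of the arrays labelled knockout, on which Pax8 did not fall.

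**Figure D1:**
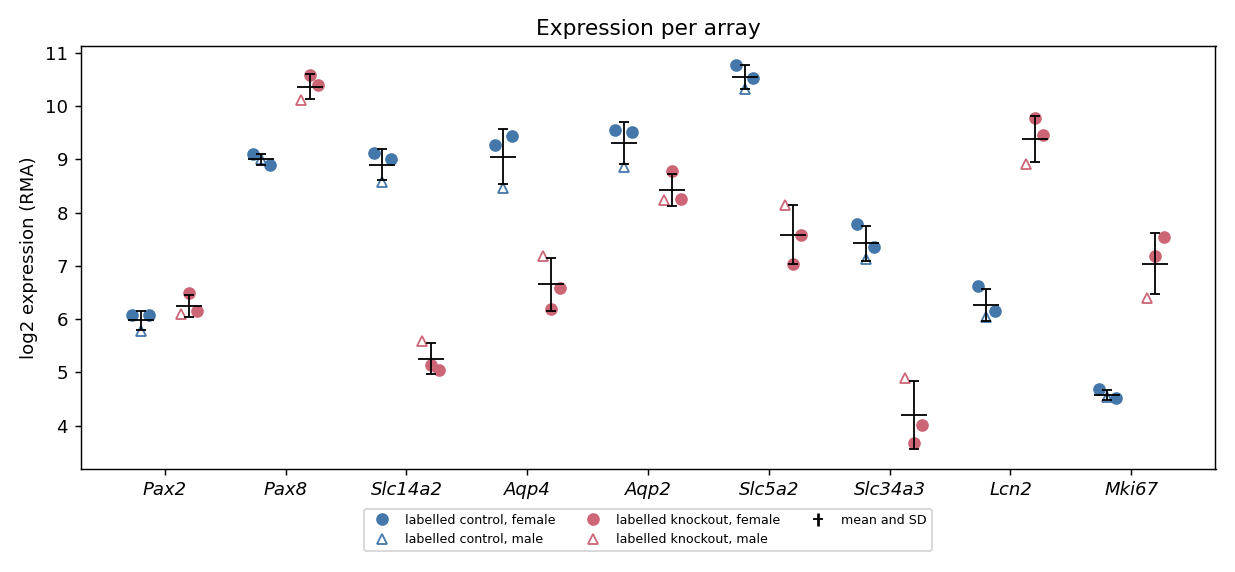
Log2 expression (RMA) of 9 genes on each array, with controls in blue, arrays labelled knockout in red, circles for females and open triangles for males; black lines give the group mean and SD (n = 3). Pax8 lies higher on every array labelled knockout, while Slc14a2, at 5.26 against 8.90, lies lower.

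Between the arrays labelled knockout and the controls, 1596 of 22180 genes passed, 913 higher and 683 lower, and 326 of them changed at least 2-fold (191 higher, 135 lower). The largest fall was in Slc14a2, the UT-A urea transporter (Entrez gene 27411), which was 12.5-fold lower at 5.26 ± 0.28 against 8.90 ± 0.29 log2 (SD, n = 3; adjusted p = 0.0011). The sodium-phosphate cotransporter Slc34a3 was 9.37-fold lower and Slc5a2, the glucose transporter SGLT2, 7.71-fold lower. Aldh1a3, a retinoic acid synthesising enzyme, was 7.62-fold lower, and the anion exchanger Slc4a1 5.97-fold lower. Fxyd4, a regulator of the sodium pump, fell 4.57-fold, Gsdmc3 4.62-fold and Hsd11b2, which inactivates glucocorticoids in aldosterone target cells, 4.11-fold. Chrdl1, a secreted bone morphogenetic protein antagonist, Aqp4, Dnase1 and Prss35 completed the 12 largest falls, between 5.83-fold and 4.08-fold.

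The largest rise was in Ly6f, a Ly6 family surface protein (Entrez gene 17071), 10.0-fold higher at 7.34 ± 0.56 against 4.02 ± 0.38 log2 (SD, n = 3; adjusted p = 0.0017). Lcn2, a secreted siderophore-binding protein and common marker of tubular injury, was 8.63-fold higher, at 9.38 ± 0.44 against 6.27 ± 0.30. The nuclear receptor Nr4a1 was 5.88-fold higher, the proliferation marker Mki67 5.48-fold, the fibrinogen chain Fgg 5.02-fold and the antiviral membrane protein Bst2 4.98-fold. Prc1 of the mitotic spindle midzone rose 4.31-fold. Ankrd1, the retinaldehyde dehydrogenase Aldh1a1 and the lipopolysaccharide co-receptor Cd14 rose between 4.0-fold and 4.06-fold. Ndc80 of the kinetochore and Serpina7 also rose, but their control means (3.13 and 2.60 log2) lay below 3.38, the limit used for dim genes. Counted from that limit, the rises were at least 3.92-fold and 2.40-fold, and their order among the largest is not known.

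Of all genes, 22.5% had groups that did not overlap, where chance gives 10%; of the called genes, 85.4% did. The count of called genes was 344 without control 2, 356 without control 6, 529 without knockout 5, 613 without knockout 3 and 471 without sex in the model, and the 2-fold count was 190, 167, 212, 247 and 201. Of Pax8 and the 24 largest changes, 19 of 25 kept their call with any single array left out. The calls lost in some of these fits were Nr4a1 (adjusted p up to 0.13), Serpina7 (0.052 without control 6), Chrdl1 (0.054 without knockout 3), Aqp4 (up to 0.062), Dnase1 (up to 0.098) and Prss35 (up to 0.081). The arrays also differed in brown fat signal: Ucp1, the thermogenic uncoupling protein of brown adipocytes, stood at 7.8 and 7.5 log2 on controls 2 and 6 and between 3.5 and 5.1 on the other 4 arrays. None of the 7 adipose genes passed between the groups with all 6 arrays. Ucp1 passed as lower in 2 of the 6 fits with a single array left out, and the adipose list passed in the females alone (median -0.61).

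Water and urea transport genes of the medulla and collecting duct were lower on the arrays labelled knockout. In the list of urea transporters, aquaporins and vasopressin receptors, 7 of 13 measured members fell and none rose, with a median log2 fold change of -0.65. Adjusted over the list alone, 9 fell and 1 rose. Besides Slc14a2, the falls were in Aqp4 (-2.40 ± 0.33, SE), Aqp6 (-1.98 ± 0.17), Aqp3 (-1.13 ± 0.17), the vasopressin V2 receptor Avpr2 (-1.10 ± 0.12), the vasopressin-regulated water channel Aqp2 (-0.88 ± 0.16) and Aqp11 (-0.65 ± 0.11). The log2 fold changes that did not pass were -0.51 for the UT-B urea transporter Slc14a1, -0.36 for Aqp1, -0.23 for Aqp5, -0.17 for Aqp7, and 0.24 for Avpr1a; Aqp8 did not pass either, with a control mean below the dim limit of 3.38. Camera gave an adjusted p of 2.3e-06 with the preset correlation and an adjusted p of 0.43 with an estimated correlation. Leaving out control 2 or control 6 ended the calls of Aqp2 (adjusted p up to 0.099) and Aqp3 (up to 0.072), Aqp4 was lost without control 2, control 6 or knockout 5, and Aqp11 (up to 0.090) without any of controls 2 and 6 and knockouts 3 and 5.

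Among collecting duct principal cell genes, 8 of 14 fell and 1 rose, with a median of -0.97; Fxyd4 (-2.19 ± 0.08, SE), Hsd11b2 (-2.04 ± 0.12), the peptide hormone gene Apela (-1.46 ± 0.10) and Avpr2 fell. The 1 rise was Stc1, encoding the secreted stanniocalcin (1.80 ± 0.32), named after its value was seen. Of 17 intercalated cell genes, 4 fell and 2 rose (median -0.26). The falls were Slc4a1 (-2.58 ± 0.21), Aqp6 and the ammonia transporters Rhbg (-1.87 ± 0.18) and Rhcg (-1.73 ± 0.14). Slc4a1 was also the 1 measured member of the red blood cell list. The rises, named after their values were seen, were Kit (0.55) and Dmrt2 (0.76). Of 8 thin limb genes, 5 fell, among them Slc14a2, Cryab (-1.28 ± 0.11), Corin (-1.14 ± 0.08) and Sptssb (-1.63 ± 0.29), and 1 rose (Cldn4, 0.84, named after its value was seen). The thin limb median was -0.79. Camera's adjusted p was 5.1e-05 for principal cells, 0.0026 for intercalated cells and 2.2e-05 for the thin limb, and with an estimated correlation the adjusted p was 0.44, 0.43 and 0.43. With adjustment within each list, 8 fell and 2 rose in the principal cell list, 8 fell and 2 rose in the intercalated list, and 6 fell and 1 rose in the thin limb list. The fall of Sptssb was lost without control 2, control 6 or knockout 3 (adjusted p up to 0.10). Of the rises, Stc1 and Kit were lost in 3 of 6 such fits (adjusted p up to 0.083 and 0.058), Dmrt2 in 1 (0.065) and Cldn4, whose groups overlapped, in 4 (up to 0.13).

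Proximal tubule genes were also lower. In the early segments 6 of 16 fell and none rose (median -0.41), with Slc5a2 and Slc34a3 followed by the neutral amino acid transporter Slc6a19 (-1.85 ± 0.24, SE) and the lactate transporter Slc5a12 (-1.65 ± 0.24). In the late segment 3 of 11 fell and none rose (median -0.51): the protease subunit Mep1b (-1.91 ± 0.42), Slc22a13 (-0.53 ± 0.09) and Slc5a8 (-0.51 ± 0.11). The groups overlapped for these 3 genes, and Slc22a13 and Slc5a8 also differed between the sexes; Slc22a7 differed by -2.38 ± 0.59 and did not pass (adjusted p = 0.063). With adjustment within each list, 11 fell and 1 rose in the early list and 8 fell in the late list. Camera gave adjusted p-values of 6.1e-07 (early) and 6.7e-05 (late), and the adjusted p was 0.43 for both with an estimated correlation. Leaving out control 2 or control 6 ended the calls of Slc6a19 (adjusted p up to 0.059), Slc5a12 (up to 0.070), Mep1b (up to 0.16), Slc22a13 (up to 0.082) and Slc5a8 (up to 0.12). Over the 6 fits with a single array left out, Slc5a12 was lost in 3, Mep1b in 4, Slc22a13 in 5 and Slc5a8 in all 6. Of the renin-angiotensin genes 2 of 8 fell, the proximal brush border enzyme Ace (-0.83 ± 0.14) and the receptor Agtr1a (-0.35 ± 0.07), with a median of -0.26. Camera's adjusted p was 0.0018, and adjusted p = 0.43 with an estimated correlation; 5 fell when adjusted over the list alone. Both calls were lost without control 2 or control 6 (adjusted p up to 0.090 and 0.13), and Agtr1a lost its call in all 6 such fits.

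Thick ascending limb and distal tubule genes had medians near 0. Of 13 thick limb genes 2 fell, the chloride channel subunit Bsnd (-0.79 ± 0.10, SE) and Cldn10 (-0.48 ± 0.10), and 1 rose, the calcium-sensing receptor Casr (0.35 ± 0.08). The median was 0.02, the mean -0.08 and camera's direction downward (adjusted p = 0.64). Of 14 distal convoluted and connecting tubule genes 2 fell, the calcium-binding S100g (-1.58 ± 0.13) and Kl (-0.46 ± 0.08), and 1 rose, Pvalb (0.52 ± 0.10), with a median of 0.01, a mean of -0.10 and an adjusted p of 0.64. Adjusted over the list alone, 4 fell and 3 rose in each. Only S100g of these 6 genes kept its call with any single array left out; the others reached adjusted p-values between 0.053 (Bsnd) and 0.16 (Casr), and Casr also missed the threshold after median centring (0.064). Among 10 podocyte genes 1 rose (Tcf21, 0.42) and 1 fell (Clic5, -0.51), and both lost their calls with any single array left out (adjusted p up to 0.091 and 0.077). Of 25 nephric transcription factors and developmental regulators 3 fell, Elf5 (-1.05 ± 0.13), the kidney cadherin Cdh16 (-0.59 ± 0.08) and Irx1 (-0.47 ± 0.10), and none rose; the list median was -0.07 (adjusted p = 0.19). Elf5 kept its call with any single array left out, Cdh16 lost it in 3 of the 6 fits (adjusted p up to 0.059) and Irx1 in all 6 (up to 0.13).

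**Figure D2:**
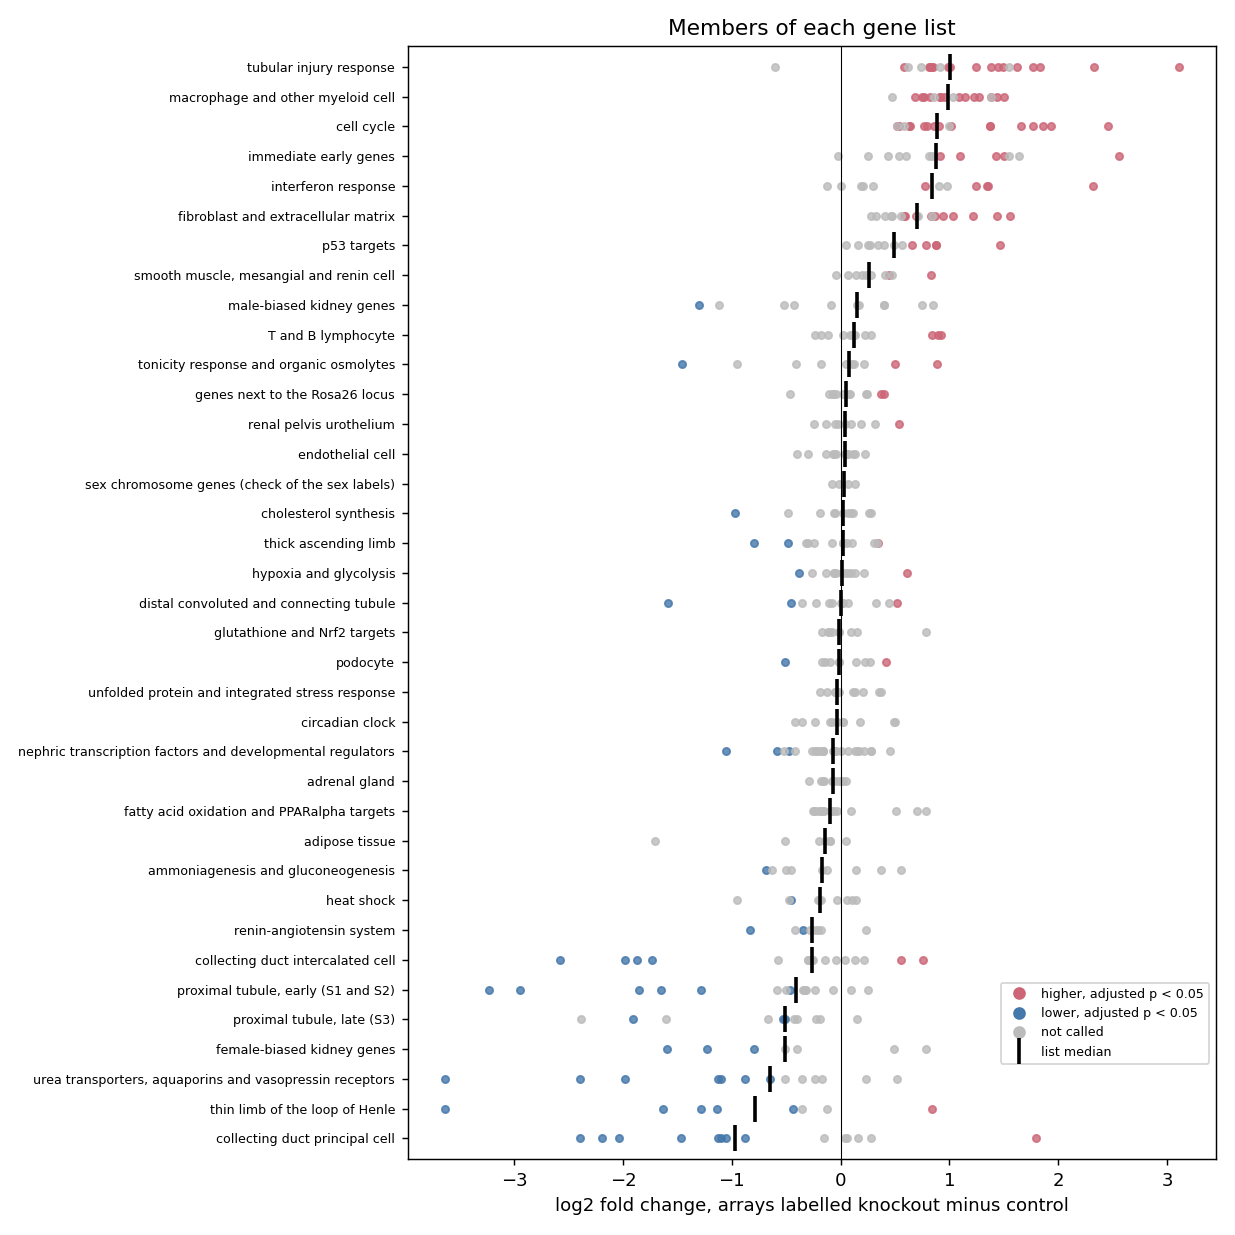
Log2 fold change (arrays labelled knockout minus control) of each measured member of 37 gene lists, 1 list per line; red points passed as higher, blue as lower, grey did not pass, and black bars mark the list median. Injury, myeloid and cell cycle medians lie at 1.01, 0.99 and 0.88, principal cell and thin limb medians at -0.97 and -0.79, and thick limb and distal tubule medians at 0.02 and 0.01.

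Genes of the tubular injury response were higher on the arrays labelled knockout: 16 of 21 rose and none fell, with a median of 1.01. Lcn2, the fibrinogen chains Fgg and Fga (1.84 ± 0.08, SE), clusterin Clu (1.45 ± 0.08) and ceruloplasmin Cp (1.62 ± 0.15) led the list. Havcr1, the injury marker KIM-1, stood at -0.60 ± 0.36 and did not pass (adjusted p = 0.40); it is named after its value was seen. Of 18 fibroblast and matrix genes 10 rose and none fell (median 0.70), led by the collagens Col1a1 (1.56 ± 0.10) and Col3a1 (1.43 ± 0.11), fibronectin Fn1 (1.21 ± 0.11) and the collagen cross-linking enzyme Lox (1.04 ± 0.09). Adjusted over the list alone, 20 and 17 rose. Camera's adjusted p was 1.9e-19 for injury and 7.2e-15 for matrix, and with an estimated correlation the adjusted p was 0.072 and 0.40. Macrophage and other myeloid markers moved with both lists: 14 of 18 rose and none fell (median 0.99), among them Cd68 (1.27 ± 0.11), the complement genes C1qa (1.44 ± 0.16) and C1qb (1.5 ± 0.15), and H2-Aa (0.95 ± 0.11). Their adjusted p was 2.0e-16 and, with an estimated correlation, the adjusted p was 0.43, and 18 rose when adjusted over the list alone.

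Cell cycle genes rose in 17 of 20 cases and none fell, with a median of 0.88 and an adjusted p of 6.5e-18 (adjusted p = 0.43 with an estimated correlation). Mki67, topoisomerase Top2a (at least 1.72, counted from the limit of 3.38), cyclin Ccna2 (1.86 ± 0.25, SE) and the replication helicase subunit Mcm5 (1.38 ± 0.08) were among them; Ccna2 was lost without control 2 (adjusted p = 0.058). Of 13 p53 targets 5 rose and none fell (median 0.49), among them the cell cycle inhibitor Cdkn1a (1.46 ± 0.17), Trp53inp1 (0.88 ± 0.14), Sesn2 (0.87 ± 0.13) and Pmaip1 (0.78 ± 0.14), with an adjusted p of 3.7e-07 (adjusted p = 0.43 with an estimated correlation). With single arrays left out, Trp53inp1 and Sesn2 lost their calls in 4 of 6 fits and Pmaip1 in 5 (adjusted p up to 0.088). Of 12 interferon response genes 5 rose and none fell (median 0.84), among them Bst2, the chemokine Cxcl10 (1.35 ± 0.13), Oasl2 (1.25 ± 0.21) and Usp18 (0.78 ± 0.15), with an adjusted p of 3.1e-06 (adjusted p = 0.43 with an estimated correlation). Oasl2 lost its call in 3 of 6 such fits (adjusted p up to 0.075) and Usp18 in 5 (up to 0.11). Immediate early genes, which respond within minutes to stimuli that include handling of tissue, rose in 5 of 14 cases and none fell (median 0.88; adjusted p = 9.0e-08, and adjusted p = 0.43 with an estimated correlation). They included Fos (at least 1.34, counted likewise), Jun (1.51 ± 0.22), Ier3 (1.10 ± 0.19) and Junb (0.91 ± 0.16). Their median against the control mean was 1.45 on knockout 3, 0.80 on knockout 5 and 0.38 on knockout 1. Without control 6, Jun (adjusted p up to 0.074), Junb (up to 0.10) and Ier3 (up to 0.093) no longer passed, and without control 2 Jun and Junb did not. Junb lost its call in 3 and Ier3 in 4 of the 6 fits with a single array left out. By adjustment within each list, 20 cell cycle, 9 p53, 7 interferon and 11 immediate early genes rose.

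Smooth muscle, mesangial and renin cell genes rose in 2 of 10 cases, Mylk (0.44 ± 0.08, SE) and Tagln (0.83 ± 0.15), with a median of 0.26 (adjusted p = 0.0026, and adjusted p = 0.43 with an estimated correlation; 3 rose when adjusted over the list alone). This list missed the threshold in the females alone, and both genes lost their calls there. Mylk lost its call in all 6 fits with a single array left out and Tagln in 5. In the lymphocyte list 3 of 13 rose, Cd4 (0.89 ± 0.12) and the antibody genes Jchain (0.92 ± 0.14) and Ighm (0.84 ± 0.17), but the list did not pass (adjusted p = 0.074). With single arrays left out, Cd4 lost its call in 2 of 6 fits (adjusted p up to 0.055), Jchain in 4 (up to 0.071) and Ighm in 5 (up to 0.13). Ighm lay at 12.1 and 11.1 log2 on the male arrays and between 9.6 and 10.8 on the females. The lists for endothelium, urothelium, adrenal gland, adipose tissue, tonicity response, heat shock, unfolded protein response, circadian clock, hypoxia, fatty acid oxidation, cholesterol synthesis, Nrf2 targets and ammoniagenesis did not pass, with medians between -0.19 and 0.08. Single calls within them included the osmolyte transporter Slc6a12 (-1.45 ± 0.28), the sterol demethylase Cyp51 (-0.97 ± 0.14), Slc38a2 (0.89 ± 0.15), Krt7 (0.54 ± 0.08), Hsph1 (-0.46 ± 0.09), Egln3 (0.61 ± 0.12), Pdk1 (-0.38 ± 0.08) and Slc9a3 (-0.68 ± 0.14), each lost without control 2 or control 6. Pdk1 was lost in all 6 fits with a single array left out. Slc6a12, Slc38a2, Krt7, Hsph1, Egln3 and Slc9a3 were each lost in 4 of them. Of 12 neighbours of the Rosa26 locus, where the Cre gene sits, 2 rose, Rad18 (0.40 ± 0.08) and Camk1 (0.37 ± 0.08), and both missed the threshold after median centring (adjusted p = 0.053 each) and with any single array left out.

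In total 15 of 37 lists passed with the preset correlation, 8 upward and 7 downward. Some lists share members, so these are not independent results. Of the falls among urea transporters and aquaporins, Aqp2, Aqp3, Aqp4 and Avpr2 are also in the principal cell list. Aqp6 is also in the intercalated cell list and Slc14a2 in the thin limb list. Tagln is in both the matrix and the smooth muscle lists. With an estimated correlation 0 passed, the smallest adjusted p was 0.072 (injury) and 1 list had an unadjusted p under 0.01. The estimate rests on 3 residual degrees of freedom and was -0.045 for injury and 0.79 for myeloid cells. The adjusted p of 0.43 is a single value that the adjustment gave many lists, among them heat shock, which passed with neither correlation. Failing with the estimate therefore decides little about a single list. By fry, which tests whether a list's genes move one way on balance, 7 of the 37 lists passed. They were injury (fry adjusted p = 3.2e-05), matrix (0.023), thin limb (0.034), renin-angiotensin (0.034), cell cycle (0.035), principal cells (0.041) and intercalated cells (0.044). Among those that missed the threshold were myeloid cells (0.051), urea transporters and aquaporins (0.056), and late (0.061) and early (0.074) proximal tubule. Other groupings of the same 6 arrays also shifted many lists with the preset correlation. The highest count was 15 with both males in the same group and 13 with 1 male per group. The counts of called members therefore carry more of the description than the p-values of the preset correlation. They stand beside a share over all genes of 1596 called in 22180, or 1909 in 14787 without the dim genes. The counts were not tested against that share, and lists with few called members may lie near it. Of the 84 called genes named from the lists, 35 kept their call with any single array left out.

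**Figure D3:**
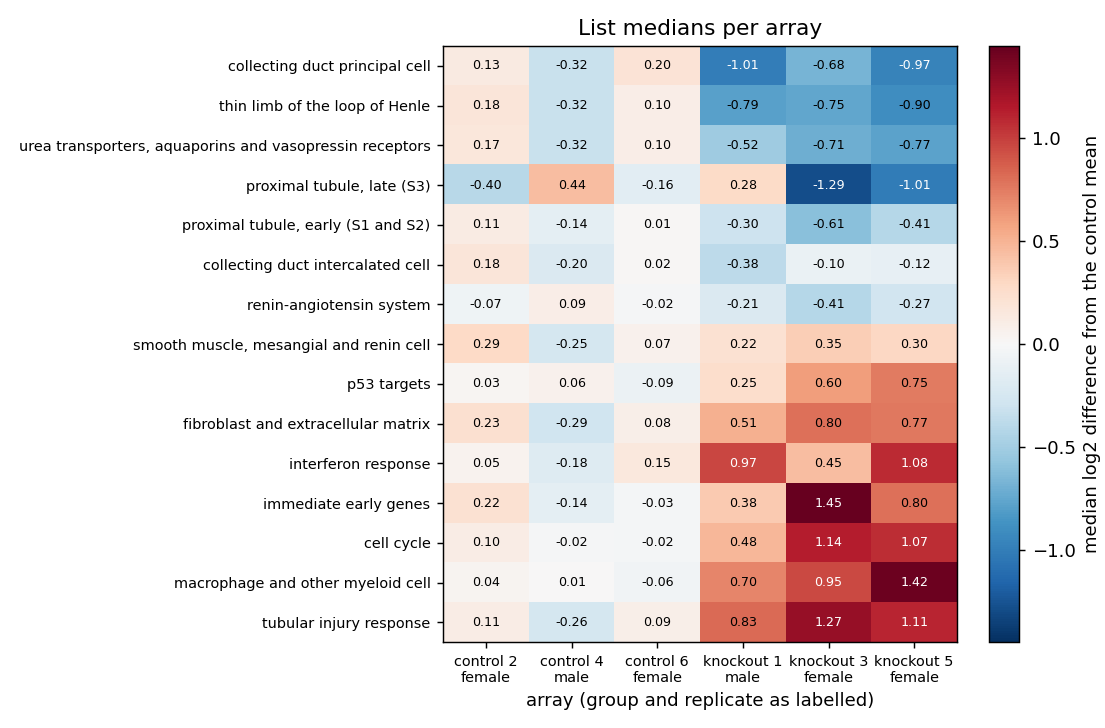
Median log2 difference from the control mean of the members of the 15 lists that passed with the preset correlation, for each array; red is higher and blue lower. The injury list lies at 0.83, 1.27 and 1.11 on the arrays labelled knockout 1, 3 and 5, while the late proximal tubule list differs by sex: it lies at 0.28 on the male knockout 1 and 0.44 on the male control 4, and at -1.29 and -1.01 on the female knockouts 3 and 5 against -0.40 and -0.16 on the female controls 2 and 6.

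The sexes differed in 415 genes over both groups, 278 higher in males and 137 higher in females, and 158 of them at least 2-fold. Where the mean of the lower sex lay below the limit of 3.38, the fold is counted from that limit, given as at least, and has no rank. The organic anion transporter Slco1a1 was at least 107-fold lower in females (3.21 ± 0.70 log2, SD, n = 4, against 10.12, n = 2) and Pzp at least 35.8-fold. The cytochrome Cyp2j13 was 96.2-fold lower and the amino acid transporter Slc7a13 85.8-fold. Eif2s3y, Uty and Kdm5d lie on the Y chromosome, which females lack, so their female values are array background and only check the sex labels. Higher in females were the X-inactivation transcript Xist (at least 73.5-fold), Cyp4a14 (9.82-fold), the efflux pump Abcc3 (5.72-fold), the carbonyl reductase Cbr1 (5.13-fold) and Abcb1b (4.88-fold). Adjusted p-values of these 12 genes lay between 2.7e-06 and 0.039. With 2 males in all, the count was between 129 and 177 with any single array left out, and 908 with the trended robust prior.

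Whether the genotype difference depends on sex was tested with a genotype by sex term. It passed for 1 gene, Ugt2b37, a glucuronosyltransferase. Ugt2b37 was 3.29 log2 higher on the female arrays labelled knockout (6.55 against 3.25, n = 2 each) and 0.47 lower on the male one (9.64 against 10.11, n = 1 each), a difference of 3.76 ± 0.19 (SE; adjusted p = 0.029). The female control level lay below the limit of 3.38, so the size of this difference is uncertain. The next 4 genes did not pass: the kallikrein Klk1b24 (-4.11), Mfsd2a (-2.83) and Ugt2b5, each with an adjusted p of 0.053, and Slc22a28 (-2.47; adjusted p = 0.079). No size is given for Ugt2b5, since its male arrays (2.73 and 2.74 log2) and control females (1.87) lay below that limit. Unadjusted, 1551 genes had a p under 0.05. The gene count was 0 without control 2 or control 6, 4 without knockout 3 or knockout 5, and 12 with the trended robust prior. Each group holds 1 male, whose spread is assumed to be that of the females. Male-biased genes fell in 1 of 11 cases (Slc22a30, at 5.97 against 7.14 log2 in the male pair and near or below the limit of 3.38 on every female array; median of the list 0.15, mean -0.07, camera downward with adjusted p = 0.92). Female-biased genes fell in 3 of 7 cases, Slco1a6 (-0.80), Hao2 (-1.22) and Slc22a29 (3.29 against 4.89 log2, the former below the limit, with overlapping groups), with a median of -0.51 and an adjusted p of 0.066. These 3 calls were lost without control 2, control 6 or knockout 3 (adjusted p up to 0.17), and those of Hao2 and Slc22a29 also without knockout 5. Adjusted over the list alone, 3 fell and 2 rose in the male-biased list and 3 fell in the female-biased list.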

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

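The tests of explanations, other than the regroupings of the arrays, were chosen after the results were seen; the test of the lists for dependence on sex was also added later, and 2 of the tests replaced earlier ones whose outcomes, given below, were already known. Ugt2b37 differed in its genotype effect between the sexes by 3.76 on the log2 scale, a size that is uncertain because its female controls (3.25) lay below the dim limit of 3.38. By camera with the preset correlation, 14 lists also differed, and 0 did with an estimated correlation; by fry 1 list differed, the female-biased genes (adjusted p = 0.033). The median difference, female minus male effect, was -1.52 for adipose tissue, -1.38 for female-biased genes, -0.48 for early and -0.35 for late proximal tubule, -0.46 for urea transporters and aquaporins, -0.39 for principal cells, -0.32 for the thin limb, -0.47 for interferon response, -0.37 for smooth muscle, -0.24 for endothelium and -0.16 for nephric transcription factors. It was 0.55 for cell cycle, 0.46 for p53 targets and 0.42 for myeloid cells. In data outside the gene tests, 43 of the 17824 clusters without a single gene symbol were higher on the arrays labelled knockout, and 19 were lower, in a test of all 41345 clusters.

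The rise of Pax8 on the arrays labelled knockout is not what loss of its whole transcript would give. A larger share of tubule cells is argued against by the tubule segment lists. Their median log2 fold changes lay between -0.97 (principal cells) and 0.02 (thick limb), against 1.36 ± 0.12 for Pax8. A set of 13 tubule epithelial genes, which need not cover all segments alike, had a median of 0.043 and ran from -0.59 to 0.85. How far the value comes from exons outside the deleted part stays open, since Pax8 has 1 cluster over the transcript and no value per exon. A transcript that persists or rises after loss of the protein could then account for the rise. An exchange of the whole groups also stays open. Xist and the Y-linked genes matched the labels on 6 of 6 arrays, but cannot show an exchange within a sex. An exchange of only some arrays is argued against, provided that the genotype changes expression. The labelled split gave 1596 genes, and the highest count of any other split was 0. These explanations and the effect of the genotype cannot be told apart here.

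Lower principal cell and thin limb genes (median of 22 genes, -0.97) stood beside lower proximal tubule genes (median of 27 genes, -0.47). For the former, 3.70% of 27 thick limb and distal tubule genes, 1 gene, lay at or below their median. That is under the bound set for arguing against a smaller share of all tubule cells. The bound does not settle the question, since the quartiles of the 22 genes (-1.42 and 0.0008) overlapped those of the 27 (-0.27 and 0.09). For the proximal genes the share was 11.1%, 3 genes, which leaves that explanation open. This test and its bounds took the place of a two-sided permutation test over genes (100000 resamples), which had argued against the explanation for both groups. It had given a difference of medians from the same 27 genes of -0.48 (permutation p = 0.00016) for the proximal genes and of -0.31 (permutation p = 0.037) for 39 collecting duct and thin limb genes. Those 39 included the intercalated cell genes, which were then left out; with them kept in, 25.9% of the 27 genes, 7 genes, lay at or below the median of -0.30, which would have left the explanation open for this group too. The permutation treated genes as independent, which they are not, and the answer for both groups depends on the form of the test. Less inner medulla in the bisected kidneys also stays open for the principal cell and thin limb genes: urothelial genes of the renal pelvis had a median of 0.045, but the pelvis need not be sampled in step with the medulla. The genotype named by the labels remains an untested biological explanation, and it includes the Cre recombinase, which the controls lack.

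The late proximal tubule list had a median genotype effect of -0.20 in the male pair and -0.56 in the females, a difference that did not pass with an estimated correlation (adjusted p = 0.58) or by fry (adjusted p = 0.40), and the effect on Slc22a13 was larger in the male pair (-0.59 against -0.50). A weaker response overall in knockout 1 could contribute. The first test of this took 320 other genes changed at least 2-fold: the male effect was 0.68 of the female one in the median (quartiles 0.49 and 0.93) and the smaller in 251 genes, under the bound of 0.75 set for it, so it favoured that explanation. It was then replaced by the tubular injury list, because selecting called genes weights the females, who are 2 of 3 arrays per group. That list gave a ratio of 0.94, with a 95% bootstrap interval over genes from 0.74 to 1.20, which decides neither way. The interval treats genes as independent and does not measure the spread between samples. The replacement was made with the first outcome known, so a weaker response overall stays a live explanation. Sex of the animal stays open as well, because each group holds 1 male, so that sex and the single animal cannot be told apart.

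Regrouping 3 against 3 arrays makes 10 splits, too few for a share under 0.05. The real split gave 1596 genes and 326 genes with at least 2-fold change, where the highest of the others gave 0 and 0, so 1 of the 10 splits was as large for each. For the lists, 2 of the 10 splits were as large: the real one gave 15 and the split of knockouts 1 and 5 with control 4 against the rest also gave 15. That split puts both males in the same group. Among the other splits with 1 male per group, as in the real one, the highest count was 13.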

How the results depend on the processing

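The alternatives were planned before the data were examined, except those of the list test by sex and of the families, and leaving out arrays in the sex tests and for 4 genes named later. No paired analysis was possible because the groups share no replicate numbers. Pax8 kept its direction and call under all 14 alternatives and Pax2 stayed uncalled. Among the named and listed genes, no called gene changed direction, and no called list did; direction under the alternatives was not tabulated for each of the other called genes.

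The count of 1596 genes became 471 without the sex term, 302 with every row tested (more tests and unnamed clusters), and 344 to 1249 with 1 array left out; the 2-fold count of 326 became 201 without the sex term and 167 to 453 with 1 array left out. Leaving out knockout 1 or control 4 gives the females-only fit (1249 and 453), as the lone male is then fitted exactly. The count was 2162 with the trended robust prior and between 1530 and 1909 under the other alternatives; the share called higher was 57.2%, and 49.4% after median centring. The 15 lists became 0 with camera's estimated correlation, 7 with fry, and 15 to 17 under the alternatives that keep the preset correlation. The 14 lists differing by sex became 0 with an estimated correlation and 1 with fry. The 415 genes differing between the sexes became 908 with the trended robust prior and 129 to 177 with 1 array left out; the 1 gene with a sex-dependent effect became 12 with that prior and 0 to 4 with 1 female array left out, and that term could not be fitted without either male. Fewer arrays lower the degrees of freedom; the cause was not tested for the other changes. Of 3139 values of named genes under alternatives, 2501 kept their side of the threshold, 48 gained it and 12 uncalled ones turned sign. Of the 2180 values of genes called in the main fit, 578 lost the call. The females-only fit and those without knockout 1 or control 4 are the same fit and were each counted. Leaving out genes with a mean log2 below 3.38 gave 1909 genes.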

Other observations

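The gene families below were tested after the data were seen, by symbol, and their members were named after their values were seen. Organic ion transporters of the Slc22 family were lower on the arrays labelled knockout: 9 of 24 genes fell and none rose, with a median log2 fold change of -0.54 and a camera adjusted p of 8.3e-06 (adjusted p = 0.85 with an estimated correlation). The groups overlapped for 6 of the 9. They included Slc22a28 (-2.78; -3.61 in the females and -1.13 in the male pair), the organic cation transporter Slc22a2 (-1.23) and the urate transporter Slc22a12 (-0.70). Acyl-CoA thioesterases of the Acot family fell in 5 of 12 cases and none rose (median -0.37; adjusted p = 0.85 with an estimated correlation), led by Acot3 (-1.43). Annexins, calcium-dependent membrane-binding proteins, rose in 7 of 11 cases and none fell (median 0.56; adjusted p = 0.85 with an estimated correlation), led by Anxa3 (1.38) and Anxa13 (1.28). Hoxb genes rose in 3 of 10 cases, Hoxb9 (0.59), Hoxb7 (0.45) and Hoxb8 (0.44), with a median of 0.35 (adjusted p = 0.85 with an estimated correlation); Hoxb8 missed the threshold after median centring (adjusted p = 0.051). Over all Slc genes measured, 47 of 361 fell and 11 rose, beside 683 and 913 of all 22180 genes.

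Antibody light chain genes of the Igkv family rose in 4 of 13 cases and none fell (median 0.995; adjusted p = 0.85 with an estimated correlation). The groups overlapped for 3 of the 4 called genes, in which both male arrays stood above every female one. Of the 4, 1 kept its call with any single array left out, and the other 3 lost it in at least 4 of 6 such fits. In all, 15 of 252 families passed with the preset correlation, 18 after quantile normalization and 23 after median centring, in each case without a change of direction among the 15; 0 passed with an estimated correlation, where every adjusted p of the 15 was 0.85. Of the other genes named here, Acot3 and Anxa3 kept their calls with any single array left out, and the rest lost them without control 2 and without control 6. Hoxb7 and Hoxb8 lost theirs in all 6 such fits, and Slc22a28, Slc22a2 and Slc22a12 in 4.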
